A study of Mus musculus with 20 samples.

How the data were processed

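RNA was measured in 20 libraries of mouse cells, 10 from embryonic stem cells (ESC) and 10 from ESC-derived presomitic mesoderm colonies (iPSM). In each cell type the libraries came from 3 kinds of line: a control line without an inducible transgene, lines in which doxycycline (dox) switches on Clock and Bmal1 (the mouse symbol of Bmal1 is Arntl), and lines in which it switches on Clock with a dominant-negative Bmal1 (ClockBmal1DN). ESC were given 500 ng/mL dox for 6 hours and iPSM 1000 ng/mL for 2 hours, each beside an untreated library of the same clone. The lines with Clock/Bmal1 were clones 1 and 7 in ESC and clones 12 and 20 in iPSM, and those with ClockBmal1DN were clones 5 and 6 in ESC and clones 7 and 19 in iPSM. The control line had 1 library with and 1 without dox in each cell type. The iPSM lines carry a luciferase reporter driven by the Hes7 promoter. Per the labels, the libraries were stranded total-RNA libraries read as paired ends on a NovaSeq.

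The authors' notes name bcl2fastq, STAR 2.7.2a and HOMER with the mm10 genome. The deposited tables, 1 per cell type, hold for each of 55421 transcripts a gene-body read count in steps of 0.5. These expected counts (expected_counts) were made by the authors from reads aligned with STAR and counted over gene bodies with HOMER, with no normalisation per the file headers (a normFactor of 1.00). In addition, the authors' second set of columns holds the same counts as rpkm, scaled by the gene body length with introns and by the total in the header. Recomputing the deposited rpkm values from the counts gave the same value within 1% plus 0.001 for 100% of the entries. Of all counts, zeros included, 18.1% ended in 0.5, and all counts were rounded to whole numbers before fitting. The transcript order was the same in both tables, 113 symbols occurred more than once, and starts were 1-based, equal to GENCODE vM21 for 54890 transcripts. Reads over genes nested in another gene on the opposite strand had an upper-quartile density ratio of 0.0161 in ESC and 0.0228 in iPSM, against 0.676 and 1.03 on the same strand, so the counts were treated as stranded. The tables count reads over the whole gene, so the transgene's Clock and Bmal1 reads add to the endogenous genes' counts and the 2 sources were not separated.

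Intervals and floors rest on counts summed over the libraries of a group, so they cover counting error only and not the spread between clones. The reads carry no molecular identifiers. A fold against a group with no reads is a lower bound computed with 3 counts over the group, and with 1 to 3 counts a ratio with its exact 95% counting interval is given in place of a fitted fold.

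All 10 libraries of a cell type were fitted together as 6 groups with edgeR 4.0.16 under R 4.3.3 (TMM factors, filterByExpr by group, estimateDisp, glmQLFit and glmQLFTest with default settings), which leaves 4 residual degrees of freedom, all from the 4 groups with 2 clones. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values for genes are from edgeR unless another tool is named. The standard error (SE) is the log2 fold change divided by the square root of F. The contrasts were dox against untreated in the Clock/Bmal1 clones, the same in the ClockBmal1DN clones, the difference of these 2 effects, and the untreated Clock/Bmal1 against the untreated ClockBmal1DN clones. The difference of the Clock/Bmal1 effect between iPSM and ESC was tested in 1 fit of all 20 libraries and 12 groups. With 2 clones per group no split of the samples was permuted. The control line has no replicate, so its values are log2 ratios of TMM-normalised counts scaled to the library total (CPM) with a prior count of 2 and no test. CPM values are given as mean ± SD of the 2 clones.

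The 22 gene lists (489 genes) were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast, 132 tests over the 6 dox contrasts. The lists were circadian E-box targets, other circadian clock components, the Per1-Hes7 neighbourhood, Notch signalling and segmentation clock, Wnt signalling, FGF and MAPK signalling, immediate early genes, presomitic mesoderm, somite, naive pluripotency, primed pluripotency and early differentiation, neural, lateral, intermediate and cardiac mesoderm, fibroblast feeder, two-cell-like, integrated stress response, unfolded protein response, p53 targets, cell cycle, mitochondrially encoded, hypoxia and glycolysis, and cholesterol synthesis. The lists, contrasts, tests and alternative settings were fixed before the data were examined, and so was the rule for the genes named. That rule takes Clock, Arntl, Per1, Per2, Nr1d1, Dbp, Hes7 and Lfng always. It adds the 8 largest rises and 8 largest falls among genes that passed with the same sign in both clones, a mean of at least 1 CPM in a group and a symbol that is not provisional. From each list it adds up to 4 members that passed, by smallest p, or up to 2 as values where none passed. For the untreated contrast it takes 4 genes each way, and for iPSM minus ESC the fixed genes and the circadian, Notch, Wnt and FGF and MAPK lists. A gene chosen after its values were seen is named as such.

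The alternative settings were relative log expression (RLE) factors in edgeR, no composition factors, no low-count filter and a mean of at least 1 CPM. They also held the DESeq2 1.42.0 Wald test and limma-trend on log2 of RPKM plus 1 (limma-voom for iPSM minus ESC). The rest were only the groups compared, each library left out in turn and a clone block. For the lists they were an estimated correlation, fry, the block and each library left out in turn. The planned fit with legacy = TRUE is the installed version's default and so is the fit reported. Added after the data were seen were legacy = FALSE, leaving out the control-line libraries with and without the block, and leaving out both libraries of ESC ClockBmal1DN clone 6, iPSM ClockBmal1DN clone 19 or iPSM Clock/Bmal1 clone 12. Where a left-out library leaves 1 in a group, that library is assumed to vary like the others. These fits have no clone block, so the treated and untreated groups then hold different clones, and differences between clones enter the dox effect. A change of sign in a gene or list that passed in neither fit was counted as no change.

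The clone numbers pair each treated library with an untreated one of the same clone, and the pairing was checked. Across genes, which are not independent replicates, the deviations of the treated and untreated libraries from their group means had a correlation of 0.668 and -0.096 in ESC Clock/Bmal1 and ClockBmal1DN, and of 0.299 and 0.297 in iPSM. The planned fit has no block, and blocked values are given where they change a call or a count by more than 1.5 times. Spread between clones was 16.9 to 117 times counting noise (chi-square per degree of freedom), and no 2 columns of a group were identical.

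The edgeR fit was tested on simulated data in which 200 genes with a mean of at least 1 CPM were changed. The data were drawn once, with no clone effect shared by treated and untreated libraries, and the rates do not cover changed genes of lower mean. In the ESC Clock/Bmal1 contrast it called 17.9% of the genes changed 2-fold, 80.6% of those changed 4-fold and 98.5% of those changed 8-fold, and 13.2% of the calls were false. In the iPSM Clock/Bmal1 contrast these values were 59.7%, 91% and 100%, with 10.2% false. For the difference between Clock/Bmal1 and ClockBmal1DN they were 1.5%, 55.2% and 81.8% in ESC and 22.4%, 76.1% and 98.5% in iPSM, and for iPSM minus ESC 6%, 68.7% and 93.9%. The false share was 11.5% and 9.7% for the differences between Clock/Bmal1 and ClockBmal1DN in ESC and iPSM and 6.7% for iPSM minus ESC, so it lay above the nominal 5% in each of the 5. A list raised in the simulation was called in both cell types, with 0 of the other 21 lists called. The simulated genes varied independently, so this does not test for false list calls where the genes of a list vary together. Sequence-level reads were not used here, so transgene reads, splice forms and single-nucleotide variants were not analysed. No columns were left out.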

Results

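Gene-level read counts were collected from 20 RNA-seq libraries, 10 of mouse embryonic stem cells (ESC) and 10 of induced presomitic mesoderm (iPSM), the tissue in which the segmentation clock oscillates and from which somites form. In each cell type, 2 clones with inducible Clock and Bmal1 and 2 clones with inducible Clock and dominant-negative Bmal1 (ClockBmal1DN) were each measured with and without doxycycline (dox). A control line gave 1 library with and 1 without dox. Library totals are given in M (mega) counts. The ESC control line held 44.7 M without and 49.4 M with dox. Clock/Bmal1 clones 1 and 7 held 56.3 and 57.3 M untreated and 40.8 and 41.1 M treated, and ClockBmal1DN clones 5 and 6 held 42.7 and 47.5 M untreated and 43.7 and 40.3 M treated. In iPSM the control line held 38.2 and 41.9 M. Clock/Bmal1 clones 12 and 20 held 47.7 and 45.1 M untreated and 41.3 and 47.8 M treated, and ClockBmal1DN clones 7 and 19 held 38.4 and 47.7 M untreated and 44.7 and 42.2 M treated. The untreated iPSM control library stood apart: it had reads over 69.4% of features, and it lay at -101.6 on a first principal component that carried 58.1% of the variance in iPSM.

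The first comparison asks which genes change in ESC within 6 hours of inducing Clock and Bmal1, the activators of the circadian clock. Genes of the clock's own feedback loops rose, together with Lfng, a Notch-modifying glycosyltransferase of the segmentation clock. Per1 and Per2, clock repressors, rose by 3.12 ± 0.463 (log2 fold change ± SE, n = 2 clones, adjusted p = 0.0273) and 4.41 ± 0.579 (adjusted p = 0.015), or 8.68-fold and 21.3-fold. Without treated clone 1 they were 2.27 (adjusted p = 0.106) and 3.82 (adjusted p = 0.0847). Nr1d1, which encodes the nuclear receptor REV-ERB alpha, and Dbp, a PAR bZIP factor driven by the clock, rose from 1.73 ± 0.0543 to 18.9 ± 4.72 CPM (10.9-fold, adjusted p = 0.0062) and from 3.82 ± 0.0584 to 51.8 ± 3.6 CPM (13.6-fold, adjusted p = 0.0159). Lfng rose 6.99-fold, from 12.9 ± 0.706 to 89.8 ± 7.78 CPM (adjusted p = 0.00298), against 13.5 CPM without and 12.7 CPM with dox in the control line. In all, 91 genes rose and 4 fell of 22500 tested with edgeR, each with the same sign in both clones. Fewer calls were made without 1 library: 9 without untreated clone 1, 23 without treated clone 1 and 7 without untreated clone 7, while 90 were made without treated clone 7. Of 22 named calls, 5, 7, 5 and 16 were kept in these 4 fits, with adjusted p up to 0.5, 0.314, 0.328 and 0.169. Arntl, Ddn, Bhlhe41, Ciart and Tef were kept in all 4. With clone as a block 158 genes passed.

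Clock and Arntl rose 12.9-fold (3.69 ± 0.594, adjusted p = 0.0377) and 67.7-fold (6.08 ± 0.499, adjusted p = 0.00225), counts that include the transgenes' reads. Other large rises were Nr4a3, an orphan nuclear receptor (6.39 ± 0.787, adjusted p = 0.01), Bhlhe41, a clock repressor also called Dec2 (6.34 ± 0.562, adjusted p = 0.003), and Nmu, which encodes the neuropeptide neuromedin U (6.18 ± 0.719, adjusted p = 0.00802). Nr4a3 was 7.82 without untreated clone 1 (adjusted p = 0.0501), 5.75 without treated clone 1 (0.0639) and 5.69 without untreated clone 7 (0.0876). Bhlhe41 was 7.56 without untreated clone 1 (adjusted p = 0.0127) and 5.68 without untreated clone 7 (0.0274). Nmu was 5.54 without treated clone 1, and without untreated clone 7, which leaves 3 untreated counts, its count ratio was 125 (95% interval 42.6 to 608). The Nmu call was lost in both fits. Ntsr2, a neurotensin receptor gene, had 0 counts in both untreated clones and was at least 94.9-fold higher with dox. The count ratio was 435 (95% interval 148 to 2110) for Ddn, 138 (24.2 to 5490) for Prok2, which encodes prokineticin 2, and 95.8 (32.4 to 468) for the homeobox gene Nkx1-1. In the control line, from 0 CPM without dox, 0.296 CPM was seen with dox for Nkx1-1, 0.254 for Ddn, 0.19 for Bhlhe41, 0.148 for Nmu and 0.127 for Nr4a3. Nkx1-1 had 2.81 and 2.33 CPM in the treated Clock/Bmal1 clones. Without untreated clone 1 the ratio was 218 (74.5 to 1060) for Ddn and 69.2 (12.1 to 2760) for Prok2. Without untreated clone 7, which leaves 0 untreated counts, they were at least 217-fold and at least 22.9-fold higher. The Ddn call was kept in both fits and the Prok2 call was lost in both. Mycn, a Myc-family transcription factor gene, fell from 133 ± 0.595 to 62.6 ± 2.35 CPM (-1.09 ± 0.169, adjusted p = 0.0315). Zfp988, a zinc-finger gene, and Dhrs7, a dehydrogenase gene, fell by 1.27 and 1.31 on the log2 scale (adjusted p = 0.0315 and 0.0471). The other fall, named after its values were seen, was Gm17546 (-3.02, SE 0.402, adjusted p = 0.0157).

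Per1 (ENSMUST00000021271.13) lies on mm10 chromosome 11 at 69098948 to 69109960, plus strand. Hes7 (ENSMUST00000024543.2), a Notch-driven repressor and oscillator of the segmentation clock, lies at 69120404 to 69124055 on the same strand, 10.44 kb beyond the end of Per1. The other fixed genes follow. Clock is ENSMUST00000202651.3 (chromosome 5, 76209868 to 76304792, minus). Arntl is ENSMUST00000047321.8 (chromosome 7, 113207465 to 113314126, plus). Per2 (ENSMUST00000069620.9, chromosome 1, 91415982 to 91459324, minus) and Nr1d1 (ENSMUST00000064941.6, chromosome 11, 98767932 to 98775333, minus) complete the set with Dbp (ENSMUST00000080885.11, chromosome 7, 45705088 to 45710203, plus) and Lfng (ENSMUST00000031555.2, chromosome 5, 140607320 to 140615545, plus). In ESC the Hes7 values were 0.373 ± 0.184 CPM with and 0.117 ± 0.0641 CPM without dox (1.66 ± 0.903, n = 2, adjusted p = 0.705). These rest on 9 and 4 counts without and 22 and 10 counts with dox in clones 1 and 7, with log2 differences of 1.41 and 1.32, and the difference did not pass.

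By list, the circadian E-box targets rose in Clock/Bmal1 ESC: 11 of 19 measured members rose, 0 fell and 8 did not pass, with 17 up adjusted over the list alone (camera p = 5.31e-33, adjusted p = 1.17e-31; adjusted p = 0.00442 with an estimated correlation). Among them were Ciart, a circadian repressor (4.59 ± 0.298, adjusted p = 0.000715), and Tef and Hlf, PAR bZIP factors (2.53 ± 0.206 and 4.50 ± 0.408, adjusted p = 0.00225 and 0.00305). Of the Notch signalling and segmentation clock list, Lfng rose and 32 of 33 did not pass, with 6 up adjusted over the list alone (up, camera p = 7.49e-05, adjusted p = 0.000824; adjusted p = 0.228 with an estimated correlation). Of 27 immediate early genes 0 passed in edgeR and 6 were up adjusted over the list alone (up, camera p = 0.000171, adjusted p = 0.00125; adjusted p = 0.704 with an estimated correlation). Values were 1.55 for Nr4a1 and 0.76 for Klf10. That call was lost without untreated clone 1 (adjusted p = 0.167) and without treated clone 7 (adjusted p = 0.393).

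The other 19 lists were not called in Clock/Bmal1 ESC. The integrated stress response list (adjusted p = 0.195) had 1 of 23 members up, Stc2, a glycoprotein hormone gene (1.91 ± 0.309, adjusted p = 0.0388), and 3 up adjusted over the list alone. The hypoxia and glycolysis list (adjusted p = 0.947) had 1 of 23 up, Ndrg1, a hypoxia-responsive gene (3.26 ± 0.466, adjusted p = 0.0236), with 4 up and 1 down adjusted over the list alone. The presomitic mesoderm list (adjusted p = 0.974) had 1 of 23 up, Lfng, with 3 up and 1 down adjusted over the list alone. No member passed in edgeR in the lists of other circadian clock components (17 measured, adjusted p = 0.524), the Per1-Hes7 neighbourhood (10, adjusted p = 0.14), Wnt signalling (46, adjusted p = 0.494), FGF and MAPK signalling (48, adjusted p = 0.647). Nor did one in somite (12, adjusted p = 0.647) and naive pluripotency (24, adjusted p = 0.367). The same held for primed pluripotency and early differentiation (14, adjusted p = 0.109), neural (12, adjusted p = 0.729), lateral, intermediate and cardiac mesoderm (17, adjusted p = 0.302), fibroblast feeder (17, adjusted p = 0.974) and the 1 measured two-cell-like gene, Zscan4d (adjusted p = 0.524). It also held for the unfolded protein response (14, adjusted p = 0.545), p53 targets (18, adjusted p = 0.767), cell cycle (28, adjusted p = 0.974), mitochondrially encoded (9, adjusted p = 0.302) and cholesterol synthesis (19, adjusted p = 0.891) lists. Adjusted over the list alone, 1 gene was up in each of the FGF and MAPK, neural and cell cycle lists, 1 naive and 2 primed pluripotency genes were down, and 0 passed in the rest. Median, mean and test differed in sign for the somite, p53, cell cycle, hypoxia and cholesterol lists. Some of these lists were called with 1 library left out: Per1-Hes7, primed and feeder (down) without untreated clone 1. Neural and stress response were called without treated clone 1. Naive, feeder (up) and stress response were called without untreated clone 7, and primed without treated clone 7. These fits have no clone block, so differences between clones enter them. The feeder markers differed more between clones 1 and 7 than with dox within either.

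Values of list members that did not pass were 2.26 ± 0.416 for Dusp2, a MAPK phosphatase gene (adjusted p = 0.0684), 3.22 ± 0.561 for the neural gene Zic1 (adjusted p = 0.0544). They were 1.60 ± 0.352 for the Wnt co-receptor gene Lrp5 (adjusted p = 0.141) and 1.14 ± 0.26 for the cell cycle inhibitor gene Cdkn1c (adjusted p = 0.16). These passed with a clone block, at 2.23 (adjusted p = 0.0143) for Dusp2, 3.28 (adjusted p = 0.0116) for Zic1, 1.53 (adjusted p = 0.0383) for Lrp5 and 1.18 (adjusted p = 0.0472) for Cdkn1c. Zic1 also went from 0 to 0.402 CPM with dox in the control line, beside 0.18 to 2.13 and 0.483 to 4.08 CPM in the clones. Without treated clone 7 Lrp5 (2.06 ± 0.313, adjusted p = 0.0435) and Tdgf1 (-1.27 ± 0.193, adjusted p = 0.0439) passed. Pluripotency genes gave -1.0 for Tdgf1, 1.09 for Esrrb, -0.59 for Dnmt3b and -0.90 for Foxd3. Other values were 0.71 for Gsk3b, -0.36 for Cul1, 1.03 for Aloxe3, 1.53 for Rnf43, 0.98 for Fgfr1, -0.64 for Tcf15, -0.82 for Olig2, 0.40 for Col1a1 and -0.36 for Twist2. Further values were 0.41 for Hsp90b1, 0.60 for Dnajb9, 1.23 for Gdf15, 0.35 for Bbc3, 0.73 for Cenpe, 0.81 for mt-Nd4, 0.63 for mt-Cytb and -0.30 for Cyp51. The cardiac gene Gata5 was at least 17.9-fold higher, and the kidney gene Pax2 had a count ratio of 18.4 (95% interval 2.8 to 777), with 0 to 0.212 CPM in the control line.

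The second comparison asks what Clock with dominant-negative Bmal1 does in ESC. Arntl rose 57.4-fold (5.84 ± 0.493, n = 2 clones, adjusted p = 0.0145), a count that includes the transgene's reads. It was the 1 gene of 22500 that passed in edgeR, with 900 at an unadjusted p under 0.05 and 6 in DESeq2. Clock values were 912 ± 831 CPM with and 37.7 CPM without dox (4.60 ± 0.62, adjusted p = 0.384). The clock targets Nr1d1 (-1.68 ± 0.388), Dbp (-2.25 ± 0.494) and Hlf (-2.23 ± 0.465) did not pass over all genes (adjusted p = 0.983 each), and 3 of the 19 circadian E-box targets were down adjusted over the list alone (camera adjusted p = 0.504). In the control line, with 1 library each and no transgene, the log2 differences with dox were -2.68 for Hlf, -0.23 for Nr1d1 and 0.25 for Dbp. Nr1d1 had 0.658 ± 0.326 CPM with and 2.11 ± 0.279 CPM without dox, and Dbp had 1.42 ± 1.2 and 6.75 ± 1.41 CPM. Values for Per1, Per2, Lfng and Hes7 were 0.24, 0.48, 0.32 ± 0.229 and 0.72 ± 1.11 (adjusted p of 0.987 or more). The Arntl call was lost without untreated clone 5 (6.00, adjusted p = 0.215) and without untreated clone 6 (5.70, adjusted p = 0.298). Its fold change was lower without treated clone 6 (5.03, adjusted p = 0.032). Without treated clone 5 Clock (5.34 ± 0.275, adjusted p = 0.00701) passed beside it, 2 genes in all.

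In ClockBmal1DN ESC 4 lists were called down by camera in limma, each with 0 members that passed in edgeR. These were the fibroblast feeder (camera in limma, adjusted p = 4.42e-07), immediate early (adjusted p = 0.00317), p53 target (adjusted p = 0.00941) and hypoxia and glycolysis lists (adjusted p = 0.0318). Each of the 4 had adjusted p = 0.84 with an estimated correlation, and 0 of their members passed adjusted over the list alone. Feeder markers, genes of fibroblasts that ESC are often grown on, differed between the ESC libraries: their mean log2 deviation was 1.782 in untreated clone 6 and -0.958 in treated clone 6, against -0.656 and -0.537 in clone 5. In Clock/Bmal1 it was 0.833 and 0.718 in untreated and treated clone 7 against -0.652 and -0.53 in clone 1, and in the control line -1.572 and -1.208. The other called lists also changed mostly in clone 6: immediate early genes went from 0.278 untreated to -0.339 treated in clone 6 and from -0.15 to -0.251 in clone 5. For p53 targets these were 0.401 to -0.179 and -0.027 to -0.079, and for hypoxia genes 0.098 to -0.276 and -0.013 to -0.116. Col1a2, a collagen gene of that list named after its values were seen, had 202.7 CPM in untreated and 26.47 CPM in treated clone 6, 110.1 and 98.25 CPM in Clock/Bmal1 clone 7, and 24.02 to 46.15 CPM in the other 6 libraries. Without untreated clone 6 none of the 4 passed, with adjusted p = 0.814 for feeder, 0.327 for immediate early, 0.509 for p53 and 0.0834 for hypoxia genes. The hypoxia list also failed without untreated clone 5 (adjusted p = 0.242), treated clone 5 (adjusted p = 0.0828) and treated clone 6 (adjusted p = 0.19). Without treated clone 5 the immediate early (adjusted p = 0.0747) and p53 lists (adjusted p = 0.0828) failed too. The other 18 lists had adjusted p of 0.356 to 0.951, and median, mean and test differed in sign for the circadian, Wnt, naive pluripotency, lateral mesoderm and cholesterol lists. The cell cycle list was called without treated clone 6 (adjusted p = 0.00133). Member values included -1.67 ± 0.593 for Col1a1, -2.31 for Prrx1, -1.07 for Ier3, -1.09 for Gadd45g, -0.77 for Phlda3, -0.77 for Bnip3, -0.60 for Dll1, -0.81 for Ccnd1 and 0.90 for Fgfr3.

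The difference between the Clock/Bmal1 and ClockBmal1DN effects in ESC asks which responses need an active Bmal1, and the 2 effects share no control library. In edgeR 13 genes had a higher and 0 a lower effect with Clock/Bmal1 (1070 at an unadjusted p under 0.05), circadian targets and others among them. The difference was 6.72 ± 0.605 for Hlf (adjusted p = 0.0176), 6.01 ± 0.702 for Dbp (adjusted p = 0.0295), 5.12 ± 0.541 for Nr1d1 (adjusted p = 0.0251), 3.91 ± 0.383 for Ciart (adjusted p = 0.0176) and 2.49 ± 0.327 for Lfng (adjusted p = 0.0483). It was 6.27 for Bhlhe41 (adjusted p = 0.0344), 5.01 for Spib (0.0295), 4.42 for Garem2 (0.0344) and 4.22 for Rasd2 (0.0176). In the control line without a transgene Hlf was also lower with dox (-2.68, from 1.45 to 0.19 CPM, 1 library each). It did not pass for Per1 (2.88 ± 0.625, adjusted p = 0.3), Per2 (3.93 ± 0.761, adjusted p = 0.214), Clock (-0.91), Arntl (0.24) or Hes7 (0.93 ± 1.48). The clone block gave 25 genes, among them Per1 (2.78 ± 0.366, adjusted p = 0.0419) and Ndrg1 (4.18 ± 0.45, adjusted p = 0.0185, against 4.06 ± 0.634 and 0.0941 without block). Without the control-line libraries the block gave 16 genes, with Ndrg1 passed (4.21, adjusted p = 0.0277) and Per1 not (2.82, adjusted p = 0.0523). Each left-out library lowered the count: to 0 without untreated Clock/Bmal1 clone 1 or 7, untreated ClockBmal1DN clone 5 or treated ClockBmal1DN clone 6. It was 1 without treated Clock/Bmal1 clone 1 or treated ClockBmal1DN clone 5, 2 without untreated ClockBmal1DN clone 6 and 8 without treated Clock/Bmal1 clone 7. Of 9 named calls these fits kept between 0 and 4, with adjusted p up to 0.304, and Lfng was lost in all 8. Dbp was 7.34 (adjusted p = 0.0178) and Nr1d1 5.76 (adjusted p = 0.122) without treated ClockBmal1DN clone 5, and Dbp 5.36 (adjusted p = 0.0663) without treated ClockBmal1DN clone 6.

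Of the lists, circadian E-box targets had 6 of 19 members up and 13 not passed, with 15 up adjusted over the list alone (camera p = 9.21e-33, adjusted p = 2.03e-31; adjusted p = 0.00449 with an estimated correlation). Notch signalling had Lfng up and 32 not passed, 3 up adjusted over the list alone (up, camera p = 0.00144, adjusted p = 0.00794; adjusted p = 0.456 with an estimated correlation). Immediate early genes had 0 of 27 passed in edgeR and 2 up adjusted over the list alone (up, camera p = 4.68e-08, adjusted p = 5.14e-07; adjusted p = 0.479 with an estimated correlation). Values were 2.02 for Maff and 1.26 for Klf10. The primed pluripotency (down, adjusted p = 0.0357; adjusted p = 0.479 with an estimated correlation), p53 (up, adjusted p = 0.0357; 0.614) and feeder lists (up, adjusted p = 0.000569; 0.614) were called with 0 members passed. In ClockBmal1DN clone 6 the mean deviations went with dox from 1.782 to -0.958 for feeder, from 0.401 to -0.179 for p53 and from 0.278 to -0.339 for immediate early genes. These changes enter all 3 calls, but the immediate early call was kept in all 8 fits without 1 library. The Notch call was lost without untreated Clock/Bmal1 clone 7 (adjusted p = 0.0538) and without untreated (0.0709) or treated (0.0851) ClockBmal1DN clone 5. The feeder and p53 calls were lost without untreated Clock/Bmal1 clone 1 (adjusted p = 0.175 and 0.351), treated Clock/Bmal1 clone 7 (0.458 and 0.52), untreated ClockBmal1DN clone 6 (0.743 and 0.471) and treated ClockBmal1DN clone 6 (0.0934 and 0.168). The primed call was lost without treated Clock/Bmal1 clone 1 (adjusted p = 0.192), untreated Clock/Bmal1 clone 7 (0.225), untreated ClockBmal1DN clone 5 (0.0855) and treated ClockBmal1DN clone 6 (0.286). The other 16 lists had adjusted p of 0.0772 to 0.974, and median, mean and test differed in sign for the FGF and MAPK and cell cycle lists. Of these 16, called without 1 library were hypoxia without untreated Clock/Bmal1 clone 1 (adjusted p = 0.0136), neural (0.0185), stress response (0.000456) and mitochondrially encoded (0.0288) without treated clone 1. Naive and stress response (adjusted p = 0.0176 each) were called without untreated clone 7. So were naive without untreated ClockBmal1DN clone 5 (adjusted p = 0.0229) and stress response (0.0397), unfolded protein response (0.0494) and hypoxia (0.0494) without treated clone 5.

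Before dox, 2 genes differed between the Clock/Bmal1 and ClockBmal1DN ESC clones in edgeR, with 358 at an unadjusted p under 0.05 and 9 in DESeq2. Both are non-coding RNA genes of the imprinted Dlk1-Meg3 region of chromosome 12, and both fall outside the naming rule and were named after their values were seen. Mirg (109729764 to 109749458, plus) was lower in the Clock/Bmal1 clones, with 4.91 ± 1.71 against 115 ± 26.2 CPM (-4.56 ± 0.37, adjusted p = 0.00522). B830012L14Rik (109678088 to 109714212, plus) had 2.68 ± 0.608 against 53.3 ± 13.4 CPM (-4.31 ± 0.293, adjusted p = 0.00217). The control line had 59.2 and 27.2 CPM. Without untreated Clock/Bmal1 clone 1 there was 1 call. In iPSM 0 genes passed in edgeR before dox, with 1190 at an unadjusted p under 0.05 and 25 in DESeq2, but 1779 passed without untreated Clock/Bmal1 clone 12.

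In iPSM the question is whether inducing Clock and Bmal1 for 2 hours changes the segmentation clock's genes beside the circadian ones. Circadian targets rose, and so did Hes1, Lfng, Dll4 and Ripply2, genes of Notch signalling and of somite boundary formation, while the Wnt-pathway genes Sp5 and Dkk1 fell. Without a clone block, the difference from the ClockBmal1DN effect passed for Hes1 but not for Lfng, Ripply2, Sp5 or Dkk1. Nr1d1 rose 21.5-fold, from 1.73 ± 0.616 to 37.4 ± 7.54 CPM (n = 2 clones, adjusted p = 0.000107), Per1 7.24-fold (2.86 ± 0.248, adjusted p = 0.000257), Per2 7.28-fold (2.86 ± 0.361, adjusted p = 0.00255) and Dbp 8.57-fold (3.10 ± 0.332, adjusted p = 0.000879). Hes1, a Notch-driven repressor, rose 5.97-fold from 16.5 ± 5.73 to 98.1 ± 4.44 CPM (adjusted p = 0.000543), and Lfng rose 5.09-fold from 14.3 ± 9.07 to 72.7 ± 35.8 CPM (adjusted p = 0.0253). Of 24805 genes tested in edgeR 247 rose and 7 fell, each with the same sign in both clones. The count was 678 without untreated clone 12, 293 without treated clone 12, 242 without untreated clone 20 and 83 without treated clone 20. Of 41 named calls 40, 35, 34 and 19 were kept, with adjusted p up to 0.0645, 0.202, 0.0872 and 0.574. Lfng (1.73 ± 0.434, adjusted p = 0.282), Dll4 (3.43, adjusted p = 0.242), Ripply2 (4.0, adjusted p = 0.121) and Aloxe3 (2.17, adjusted p = 0.0747) were among the 22 calls lost without treated clone 20. A fit without both libraries of clone 12 keeps only clone 20, so it has no measure of the spread between Clock/Bmal1 clones. Per2 was 3.46 without untreated clone 12 (adjusted p = 0.000642) and Lfng 3.20 without untreated clone 20 (adjusted p = 0.00189).

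Hes7, the gene whose promoter drives the reporter, had 27.9 ± 7.2 CPM with and 14.6 ± 9.72 CPM without dox (0.94 ± 0.375, 1.92-fold, n = 2, adjusted p = 0.691), a difference that did not pass after adjustment over all genes. Its log2 difference was 1.56 in clone 12 and 0.62 in clone 20. It passed with a clone block (1.08 ± 0.212, adjusted p = 0.0159). It also passed with no low-count filter (0.94 ± 0.198, adjusted p = 0.000333), a setting that raised the count of calls in every contrast. Untreated clones 12 and 20 had 7.7 and 21.5 CPM, so leaving out either shifts the baseline. The Hes7 difference was 1.86 ± 0.264 without untreated clone 20 and 0.38 ± 0.243 without untreated clone 12. The ClockBmal1DN clones had 17.6 ± 4.03 CPM with and 18.1 ± 1.94 CPM without dox, and the control line 31.0 and 25 CPM. Aloxe3, a lipoxygenase gene on the far side of Hes7 from Per1 (chromosome 11, 69125896 to 69149115, plus), rose 7.04-fold from 1.05 ± 0.24 to 7.45 ± 3.79 CPM (2.82 ± 0.411, adjusted p = 0.00627; without treated clone 20 2.17, adjusted p = 0.0747). Its gain in CPM per kb was 5.2% and 9.29% of that of Per1 in clones 12 and 20, against 5.31% and 5.66% in ESC clones 1 and 7. It was the 1 of 10 members of the Per1-Hes7 neighbourhood list to pass, also adjusted over the list alone (up, camera p = 0.0102, adjusted p = 0.0375; adjusted p = 0.553 with an estimated correlation; 0.378 without untreated clone 12 and 0.0848 without treated clone 12).

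**Figure D1:**
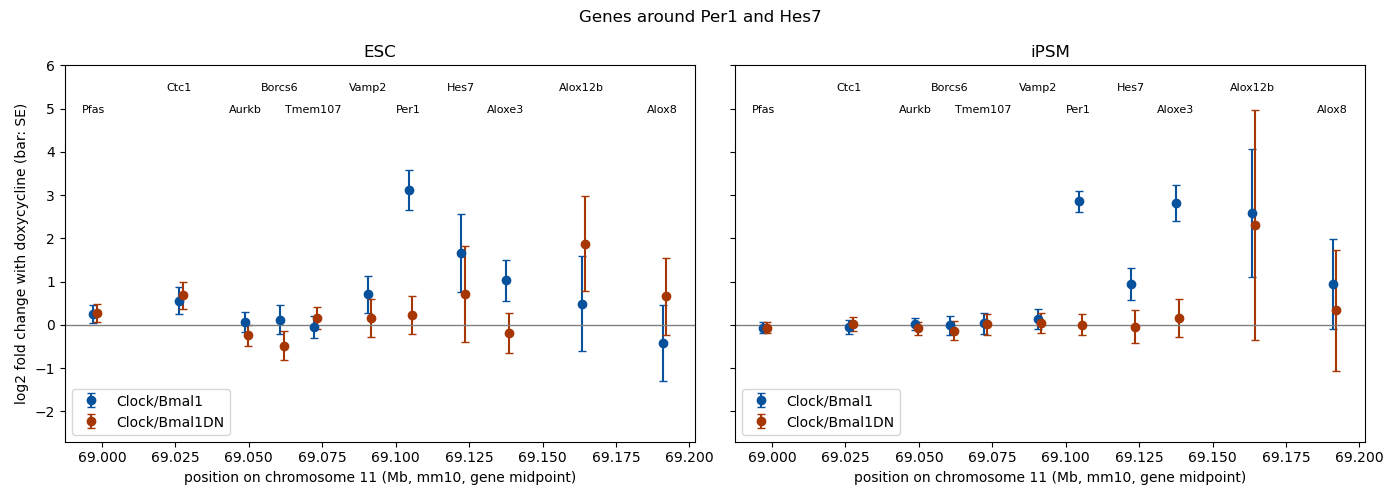
Log2 fold change with dox ± SE for 11 genes around Per1 by position on mm10 chromosome 11, for Clock/Bmal1 and ClockBmal1DN in ESC and iPSM (2 clones each). In Clock/Bmal1 iPSM Per1 lies at 2.86, Hes7 at 0.94 and Aloxe3 at 2.82, and the gene next to Per1 on its other side, Vamp2, at 0.13.

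Clock rose 20.8-fold (4.38 ± 0.18, adjusted p = 1.49e-06) and Arntl 59.1-fold (5.89 ± 0.693, adjusted p = 0.00157) in Clock/Bmal1 iPSM, transgene reads included. Large rises were Hrh3, a histamine receptor gene (7.08 ± 0.617, adjusted p = 0.000257), Onecut1, a homeobox gene (6.45 ± 0.533, adjusted p = 0.000186), and Ddn (6.11 ± 0.883, adjusted p = 0.00589). Without treated clone 20 they were 6.44 (adjusted p = 0.00263), 5.87 (0.00201) and 5.08 (0.106). Without untreated clone 12, which leaves 1 untreated count for Hrh3 and 0 for Ddn, the count ratio of Hrh3 was 269 (95% interval 48.1 to 10700) and Ddn was at least 78.2-fold higher. Ddn was 6.70 without treated clone 12 (adjusted p = 0.00248) and 5.22 without untreated clone 20 (adjusted p = 0.0095). Against 0 counts without dox, Ntsr2 was at least 66.6-fold, Bmp3 at least 62.5-fold and Nkx1-1 at least 52.2-fold higher. Bmp3 was at least 93.3-fold higher without treated clone 12, and Bmp3 and Ntsr2 at least 27.7-fold and 42.3-fold higher without treated clone 20, where both calls were lost. Count ratios were 202 (95% interval 55.6 to 1680) for Prok2 and 96.8 (17 to 3860) for Ankrd63. Prok2 gave 303 (83.2 to 2510) without treated clone 12, 109 (30 to 905) without untreated clone 20 and 88.7 (23.8 to 745) without treated clone 20. Ankrd63 gave 52.2 (9.15 to 2080) without untreated clone 20, where the Ankrd63 call was lost. Without untreated clone 12 Prok2 and Ankrd63 were at least 62.1-fold and at least 14.9-fold higher. Of the 7 falls, Ccn2 and Ccn1, targets of YAP and of serum response factor, had -1.36 ± 0.236 (adjusted p = 0.0182) and -1.12 ± 0.205 (adjusted p = 0.0247). Sp5, a Wnt target gene, fell from 74.0 ± 5.46 to 35.7 ± 1.83 CPM (-1.05 ± 0.136, adjusted p = 0.00299), and Dkk1, a Wnt inhibitor gene, had -1.33 ± 0.256 (adjusted p = 0.0327). Zfp503 (-1.15), Klhl6 (-0.93) and Pcdh18 (-0.74) also fell (adjusted p = 0.0296, 0.0187 and 0.045). Of these 7, Dkk1, Zfp503, Ccn1, Klhl6 and Pcdh18 were lost without treated clone 12 (adjusted p up to 0.202), Dkk1, Zfp503, Ccn1 and Pcdh18 without untreated clone 20 (up to 0.0872), and all 7 without treated clone 20 (up to 0.401, for Pcdh18).

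By list in Clock/Bmal1 iPSM, circadian E-box targets had 12 of 19 members up, 0 down and 7 not passed, 16 up adjusted over the list alone (camera p = 4.73e-43, adjusted p = 1.04e-41; adjusted p = 0.12 with an estimated correlation). Members included Ciart at 4.60 ± 0.242 and Bhlhe41 at 5.30 ± 0.386. Notch signalling had 3 of 34 up (Hes1, Dll4 at 3.75 ± 0.624 and Lfng) and 31 not passed, 8 up adjusted over the list alone (up, camera p = 1.35e-05, adjusted p = 0.000148; adjusted p = 0.553 with an estimated correlation). It was lost without untreated clone 12 (adjusted p = 0.114) and without treated clone 20 (adjusted p = 0.687). Dll4 was 3.11 without untreated clone 20 (adjusted p = 0.0385), and without untreated clone 12, which leaves 2 untreated counts, its count ratio was 37.7 (95% interval 10.3 to 314). Wnt signalling had 2 of 46 down (Sp5 and Dkk1), 1 up and 6 down adjusted over the list alone (down, camera p = 0.00354, adjusted p = 0.0156; adjusted p = 0.553 with an estimated correlation; 0.298 without untreated and 0.736 without treated clone 12). The presomitic mesoderm list had 2 of 28 up, Lfng and Ripply2, a somite boundary gene (5.01 ± 0.737, adjusted p = 0.00667), and 1 down, Sp5, with 2 up and 4 down adjusted over the list alone (down, camera p = 0.00102, adjusted p = 0.00561; adjusted p = 0.654 with an estimated correlation; 0.736 without treated clone 12 and 0.963 without untreated clone 20). Ripply2 was 4.16 without untreated clone 12 (adjusted p = 0.0151), and without untreated clone 20, which leaves 1 untreated count, its count ratio was 131 (95% interval 23.3 to 5200). Hypoxia and glycolysis had 3 of 23 up, Ndrg1 (4.83 ± 0.243), Pfkfb3, a glycolysis regulator (2.01 ± 0.225), and Hk2, a hexokinase gene (1.13 ± 0.227, adjusted p = 0.043), and 4 up adjusted over the list alone (up, camera p = 0.000285, adjusted p = 0.00209; adjusted p = 0.553 with an estimated correlation; 0.543 without treated clone 12). Hk2 was lost without untreated clone 12 (adjusted p = 0.0645). The naive pluripotency list had 0 of 24 passed (down, camera p = 0.0127, adjusted p = 0.04; adjusted p = 0.654 with an estimated correlation; 0.901 with the direction turned without untreated clone 12 and 0.97 without treated clone 20). Values were -0.58 for Sox2 and -0.43 for Sall4.

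The other 15 lists were not called in Clock/Bmal1 iPSM. Immediate early genes (adjusted p = 0.0576) had 7 of 27 up and 2 down, 9 up and 5 down adjusted over the list alone. Up were the AP-1 and ATF genes Junb (2.14 ± 0.159), Fosl1 (3.30 ± 0.396) and Atf3 (1.64 ± 0.211), and Maff (1.92 ± 0.222). FGF and MAPK signalling (adjusted p = 0.122) had 2 of 48 up, Dusp2 (3.26 ± 0.251, adjusted p = 0.000118) and Spry1, an FGF feedback inhibitor gene (1.32 ± 0.215, adjusted p = 0.0124), with 4 up and 4 down adjusted over the list alone. In the blocked fit the immediate early (up, adjusted p = 0.0438), FGF and MAPK (down, 0.0438) and somite lists (down, 0.044) were called. Without the block and with an estimated correlation their adjusted p was 0.553, 0.654 and 0.553. One or more members rose in the primed pluripotency (Pou3f1, 2.17 ± 0.3; list adjusted p = 0.921), integrated stress response (Stc2, 1.69 ± 0.281; 0.243), cell cycle (Cdkn1c, 0.86 ± 0.156; 0.971) and lateral mesoderm lists (Gata5, count ratio 41.9, 95% interval 14 to 206; 0.949). Gata5 gave 22.6 (7.55 to 111) without untreated and 21.2 (6.56 to 109) without treated clone 20, and its call was lost in both fits. It was at least 19.3-fold higher without untreated clone 12, where Fosl1 was 4.11. No member passed in the other circadian components (adjusted p = 0.971), somite (0.168), neural (0.172), feeder (0.561), two-cell-like (0.971), unfolded protein response (0.524), p53 (0.243), mitochondrially encoded (0.478) and cholesterol lists (0.894). Adjusted over the list alone, 4 stress response, 2 lateral mesoderm and 1 each of the primed, cell cycle, other circadian, neural and p53 genes were up. Median, mean and test differed in sign for the other circadian, lateral mesoderm, feeder, two-cell-like, stress response and cell cycle lists. Of these 15, called without untreated clone 12 were the stress response (down, adjusted p = 0.0306), cell cycle (down, 0.0306), unfolded protein response (down, 0.0328) and cholesterol lists (down, 0.0306). Without treated clone 12 the stress response (adjusted p = 0.0102) and p53 lists (0.024) were called. Without untreated clone 20 the FGF and MAPK (adjusted p = 0.0161), stress response (8.13e-08), cell cycle (0.00228) and cholesterol lists (up, 0.0161) were called. The FGF and MAPK (adjusted p = 0.0174), immediate early (0.00676) and somite lists (0.0285) were called without treated clone 20. Values that did not pass were 0.61 for Sirt1, -0.46 for Fst, 2.02 for Sox1, 3.01 for Zic1, -0.59 for Col1a2, 1.22 for Prrx1, -1.94 for Tmem92, 0.35 for Dnajb9, 0.74 for Bbc3, -0.47 for Btg2, 0.28 for mt-Nd2 and 0.24 for Insig1. The muscle gene Myod1 was at least 15.1-fold higher. Without untreated clone 12 Sirt1 (0.72 ± 0.145, adjusted p = 0.0227), Fst (-0.65 ± 0.147, adjusted p = 0.0374) and Btg2 (-0.62 ± 0.141, adjusted p = 0.0377) passed, and without treated clone 12 Sox1 (2.48 ± 0.488, adjusted p = 0.0409).

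In ClockBmal1DN iPSM, Clock rose 9.48-fold (SE 0.171 on the log2 scale, n = 2 clones, adjusted p = 2.16e-05), transgene reads included, the 1 gene of 24805 to pass in edgeR (159 at an unadjusted p under 0.05, 1 in DESeq2). Arntl was 41.8 CPM without and 887.8 CPM with dox in clone 7 but 66.0 and 153 CPM in clone 19 (3.27 ± 0.613, adjusted p = 1). Values for Per1, Per2, Nr1d1, Dbp, Hes7 and Lfng were 0.00 ± 0.238, -0.17, 0.10, -0.37, -0.04 ± 0.373 and -0.24 ± 0.416 (adjusted p = 1 each). Without treated clone 19 Arntl passed too (4.04 ± 0.305, adjusted p = 0.00153). Lists called down, with 0 members passed in edgeR or adjusted over the list alone, were immediate early genes (camera p = 4.51e-07, adjusted p = 9.92e-06; adjusted p = 0.178 with an estimated correlation), naive pluripotency (p = 3.41e-06, adjusted p = 3.75e-05; 0.551), primed pluripotency (p = 7.4e-06, adjusted p = 5.42e-05; 0.34). So were, by camera in limma, FGF and MAPK signalling (adjusted p = 0.00177; 0.551), somite (adjusted p = 0.0298; 0.34) and Wnt signalling (adjusted p = 0.0298; 0.775). The circadian targets were not called (adjusted p = 0.238), nor the other 15 lists (0.0673 to 0.966), though the block called the presomitic mesoderm (down, adjusted p = 0.00344) and cholesterol lists (up, 0.0258). Without the block and with an estimated correlation both had adjusted p = 0.904. Without treated clone 7 the FGF (adjusted p = 0.225), immediate early (0.0718), primed (0.0718), somite (0.277) and Wnt calls (0.1) were lost. The naive (adjusted p = 0.217), primed (0.0901) and Wnt calls (0.0607) were lost without untreated clone 7. The somite (adjusted p = 0.384) and Wnt calls (0.251) were lost without untreated clone 19 and the Wnt call without treated clone 19 (0.0654). Member values were -0.51 for Ccn1, -0.53 for Ccn2, -0.47 for Sox2, -0.86 for Eomes, -0.32 for Sp5 and -2.26 for Myf5. Median, mean and test differed in sign for the other circadian, Notch and two-cell-like lists. Of the uncalled lists, lateral mesoderm (adjusted p = 0.00467), unfolded protein response (0.0336), mitochondrially encoded (0.00493) and hypoxia (0.0166) were called without untreated clone 7, the last 2 with the direction turned. Mitochondrially encoded (adjusted p = 0.00374), hypoxia (0.000151) and cholesterol (0.00065) were called without untreated clone 19. Presomitic mesoderm (adjusted p = 0.00324), two-cell-like (0.0337), unfolded protein response (0.0478) and cell cycle (0.038) were called without treated clone 19.

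The effect of Clock/Bmal1 in iPSM exceeded that of ClockBmal1DN for 69 genes and was lower for 0 (edgeR, 856 at an unadjusted p under 0.05). Fitted rises of Arntl and Clock were 59.1-fold and 20.8-fold with Clock/Bmal1, against 9.65-fold and 9.48-fold with ClockBmal1DN, transgene reads included. A larger effect therefore cannot be assigned to the form of Bmal1 rather than to its level. The difference was 4.33 ± 0.448 for Nr1d1 (adjusted p = 0.00463), 2.85 ± 0.339 for Per1 (adjusted p = 0.006), 3.03 ± 0.488 for Per2 (adjusted p = 0.0301). It was 3.47 ± 0.463 for Dbp (adjusted p = 0.0122), 2.59 ± 0.341 for Hes1 (adjusted p = 0.011), 3.80 ± 0.348 for Dusp2 (adjusted p = 0.00205) and 5.01 ± 0.318 for Ndrg1 (adjusted p = 0.00016). It did not pass for Lfng (2.59 ± 0.595, adjusted p = 0.202), Hes7 (0.98 ± 0.529, adjusted p = 1), Ripply2 (5.34 ± 1.12, adjusted p = 0.129) or Clock (1.13 ± 0.223, adjusted p = 0.0867). Nor did it pass for Aloxe3 (2.65 ± 0.599, adjusted p = 0.184), Arntl (2.62, adjusted p = 0.642), Stc2 (1.60 ± 0.393, adjusted p = 0.268) or Vldlr (1.24 ± 0.376, adjusted p = 0.611). The clone block gave 132 genes, among them Lfng (2.68 ± 0.255, adjusted p = 0.00023), Ripply2 (5.36 ± 0.85, adjusted p = 0.00783), Clock (1.11 ± 0.211, adjusted p = 0.0294), Stc2 (adjusted p = 0.00469) and Vldlr (adjusted p = 0.0153). The count was 167 without untreated and 110 without treated Clock/Bmal1 clone 12, 93 and 22 without untreated and treated clone 20. It was 24 and 16 without untreated and treated ClockBmal1DN clone 7, and 16 and 18 without untreated and treated clone 19. Of 23 named calls these fits kept 23, 23, 23, 10, 12, 9, 9 and 12, and Nr1d1, Onecut1, Ciart, Dusp2, Junb and Ndrg1 were kept in all 8. Per2 was 3.63 without untreated Clock/Bmal1 clone 12 (adjusted p = 0.00291). Without untreated clone 20, which leaves clone 12 alone in the untreated group, Lfng (3.45 ± 0.481), Hes7 (1.90 ± 0.324), Ripply2 (no fold, 1 untreated count), Clock (1.17) and Stc2 (2.04) passed too. So did Clock (1.36, adjusted p = 0.0214), Aloxe3 (3.09, 0.0394) and Ripply2 (5.92, 0.0316) without treated clone 12. Clock (1.10, adjusted p = 0.0392) and Dkk1 (-1.44, 0.0413) passed without untreated clone 12, and Arntl (4.38, 0.0137) without treated ClockBmal1DN clone 7. Without both libraries of ClockBmal1DN clone 19, whose Arntl was low, 2 genes passed.

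Of the lists in that difference, circadian E-box targets had 10 of 19 members up and 9 not passed, 14 up adjusted over the list alone (camera p = 2.96e-41, adjusted p = 6.5e-40; adjusted p = 0.131 with an estimated correlation). Notch signalling had Hes1 up and 33 not passed, 2 up adjusted over the list alone (up, camera p = 8.99e-05, adjusted p = 0.00066; adjusted p = 0.939 with an estimated correlation; 0.116 without untreated Clock/Bmal1 clone 12 and 0.59 without treated clone 20). Immediate early genes had 5 of 27 up, with Junb, Fosl1, Maff and Atf3 among them, and 7 up adjusted over the list alone (up, camera p = 3.58e-05, adjusted p = 0.000394; adjusted p = 0.195 with an estimated correlation). The hypoxia list had 2 of 23 up, Ndrg1 and Pfkfb3, and 4 adjusted over the list alone, and was not called (adjusted p = 0.06). In the blocked fit the hypoxia, Per1-Hes7 neighbourhood and integrated stress response lists had adjusted p = 0.0481 each, and without the block and with an estimated correlation 0.939, 0.708 and 0.996. The other 18 lists had adjusted p of 0.12 to 0.992 without the block. Median, mean and test differed in sign for the other circadian, FGF and MAPK, presomitic mesoderm, somite, lateral mesoderm, feeder, unfolded protein response, p53, cell cycle and hypoxia lists. Without untreated Clock/Bmal1 clone 12 the presomitic mesoderm (adjusted p = 0.00128) and cholesterol lists (0.00337) were called, and without treated clone 12 the stress response list (0.00311). So were, without untreated clone 20, the stress response (2.03e-08) and cell cycle lists (0.00386), and without treated clone 20 the Wnt (0.00257), presomitic mesoderm (0.000902) and hypoxia lists (2.56e-05). Without untreated ClockBmal1DN clone 7 the neural (adjusted p = 0.0377) and hypoxia lists (9.99e-06) were called, and without treated clone 7 the presomitic mesoderm list (0.0121). Without untreated clone 19 the primed (adjusted p = 0.0126), mitochondrially encoded (0.0105) and cholesterol lists (0.0126) were called, and without treated clone 19 the hypoxia list (0.00466). Values included -0.73 for Sp5, -1.12 for Dkk1 and 0.93 for Cdkn1c, none of which passed.

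Between iPSM and ESC the Clock/Bmal1 effect differed significantly for 0 of 26689 genes in edgeR, with 1074 at an unadjusted p under 0.05, 15 in DESeq2 and 0 in limma-voom. In simulated data this comparison called 6% of the genes changed 2-fold and 68.7% of those changed 4-fold, so 0 calls does not rule out differences of the size listed here. Dose, time and parental line differ together with the cell type here. The differences (iPSM minus ESC) were -1.60 ± 0.681 for Per2 (adjusted p = 1), -1.12 ± 0.258 for Tef (adjusted p = 0.713), -0.78 ± 0.819 for Hes7 (adjusted p = 1). They were -0.52 for Lfng, 0.93 for Nr1d1, 0.63 for Clock, -0.25 for Arntl, -0.31 for Per1 and -0.72 for Dbp. List members gave -1.28 for Per3, 0.86 for Hes6, -1.31 for Dll3, -1.55 for Phlda1, -1.28 for Lrp5, -1.23 ± 0.304 for Fgfr1 (adjusted p = 0.854) and -1.69 for Dusp5. Adjusted over the list alone 3 of 19 circadian E-box targets and 1 of 48 FGF and MAPK genes had a smaller effect in iPSM, and 0 of 34 Notch and 0 of 46 Wnt genes passed. Blocked by clone, 2 genes passed, Tns4 (-3.66 ± 0.504, adjusted p = 0.046) and Spib (-4.53 ± 0.566, adjusted p = 0.0293), both outside the naming rule and named after their values were seen. Of 20816 genes tested in both cell types, 68 rose in both, of 91 up in ESC and 244 in iPSM, against 1.07 for independent lists (Fisher's exact p = 3.08e-115, two-sided). Clock and Arntl, whose counts include transgene reads, are among the 68. This comparison was made after the result was seen. Its p-value takes genes as independent, which they are not, and does not measure the spread between clones. No gene was called in opposite directions, and of 4 and 7 falls 0 were shared.

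In the control line, which has no transgene and no replicate, 150 of 14587 ESC genes with a mean of at least 1 CPM were higher and 257 lower by at least 1 on the log2 scale with dox. No test was made. In iPSM 32 of 15780 were higher and 1029 lower, in a pair whose untreated library had reads over 69.4% of features. Per1 was 6.38 CPM without and 4.38 CPM with dox in ESC, and Lfng 13.5 and 12.7 CPM.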

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

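Of the tests in this part, those of depth, of the genes around Per1, of read-through, of feeder RNA and of an outlying clone were chosen only after the result was seen, while the X to autosome ratio and the share of long silent features were set before. The differences between the Clock/Bmal1 and ClockBmal1DN effects listed here were planned, and each was singled out because a test of the difference itself passed in edgeR (adjusted p under 0.05, 2 clones against 2).

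In ESC 13 genes had a larger dox effect with Clock/Bmal1 than with ClockBmal1DN. For the clock genes and the Notch gene Lfng, the log2 differences were 5.12 for Nr1d1, 6.01 for Dbp, 6.72 for Hlf, 6.27 for Bhlhe41, 3.91 for Ciart and 2.49 for Lfng, and Hlf was also lower with dox in the control line (-2.68). For Spib, an Ets-family gene, Garem2, an adaptor gene, and Rasd2, a small GTPase gene, they were 5.01, 4.42 and 4.22. No call held in every fit without 1 library, where 0 to 8 genes passed and 0 to 4 of these 9 were kept. Bhlhe41 was 7.49 without untreated Clock/Bmal1 clone 1 (adjusted p = 0.0688) and 5.61 without untreated clone 7 (0.112). Without treated ClockBmal1DN clone 5 Nr1d1 was 5.76 and Dbp 7.34, and without treated ClockBmal1DN clone 6 Dbp was 5.36, Spib 5.63 and Garem2 5.12.

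In iPSM 69 genes had a larger dox effect with Clock/Bmal1. Fitted rises of Arntl and Clock were also larger there (59.1-fold and 20.8-fold, against 9.65-fold and 9.48-fold with ClockBmal1DN), though neither difference passed. The form of Bmal1 and its level are therefore not separated. Among clock genes the log2 differences were 2.85 for Per1, 3.03 for Per2, 4.33 for Nr1d1, 3.47 for Dbp, 5.73 for Hlf, 4.49 for Ciart and 5.35 for Bhlhe41. The homeobox gene Nkx1-1 passed with adjusted p = 0.0226 and no fold is given, since it had no counts in some of the groups. Receptor, channel and hormone genes gave 7.58 for Hrh3, 5.98 for Nmu, 5.45 for Kcnj5 and 5.45 for Gpr176, and transcription factor genes 7.24 for Onecut1, 5.91 for Nr4a3 and 2.74 for Pou3f1. Immediate early genes gave 2.4 for Junb, 3.7 for Fosl1, 1.91 for Maff and 1.81 for Atf3. The difference was 2.59 for Hes1, 3.8 for Dusp2, 5.01 for Ndrg1 and 2.27 for Pfkfb3. Only Nr1d1, Onecut1, Ciart, Dusp2, Junb and Ndrg1 were kept in all 8 fits without 1 library, in which 16 to 167 genes passed. Without untreated Clock/Bmal1 clone 12 Per2 was 3.63, Hlf 7.00 and Fosl1 4.51, and Hrh3 had 1 untreated count left, and without treated clone 12 Nr4a3 was 6.50. Without untreated clone 20 Nmu was 6.77 and Hlf 5.12, and without treated clone 20 Hrh3 was 6.94, Onecut1 6.65, Nr4a3 4.9 and Gpr176 4.75. Without treated ClockBmal1DN clone 7 Hrh3 was 8.20 and Kcnj5 4.84. Without untreated ClockBmal1DN clone 19 Nr4a3 was 4.88 and Kcnj5 4.40, and without treated clone 19 Kcnj5 was 6.44.

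The 3 genes Hes7, Per1 and Aloxe3 lie next to each other, and in Clock/Bmal1 iPSM Aloxe3 rose with Per1 while the Hes7 difference did not pass in the fit without a clone block and with the low-count filter. Read-through from Per1 at the ESC rate could not be judged as the source of the Hes7 gain in iPSM. The ESC rate rests on few counts, and the Hes7 difference in iPSM passed only in some fits. In ESC clones 1 and 7 the gain in CPM per kb was 2.09% and 2.91% of that of Per1, from gains of 13 and 6 counts. In iPSM clones 12 and 20 it was 141% and 73.8%, and the lower of these was 25.4 times the higher ESC value. With dox Hes7 went from 7.7 to 22.8 CPM in iPSM clone 12 and from 21.5 to 33.0 CPM in clone 20. Whether dox raised Hes7 beyond the spread between clones depends on the fit. The difference passed in edgeR with a clone block (1.08 ± 0.212, adjusted p = 0.0159) and not without it (adjusted p = 0.691). For Aloxe3 the gain was 5.31% and 5.66% in the ESC clones and 5.2% and 9.29% in the iPSM clones, so read-through is not excluded for the gene that passed. A rise of all genes on both sides is argued against, since the other 9 neighbouring genes had a median log2 fold change of 0.041 beside 2.82 ± 0.411 for Aloxe3, with -0.07 ± 0.124 to 0.13 ± 0.232 upstream. Whether Aloxe3 responds to Clock/Bmal1 itself or the downstream side rises as a whole stays open, with 0.94 ± 0.375 for Hes7, 2.58 ± 1.48 for Alox12b and 0.94 ± 1.05 for Alox8, none passed.

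The untreated iPSM control library had reads over 69.4% of features, and over 66.9% of olfactory receptor features against at most 11.5% in any other iPSM library. Deeper sequencing is argued against, since its total was 0.853 of the median of the other 9. For genomic DNA in the library, the X to autosome ratio of reads over features silent elsewhere was 0.272 (95% interval 0.227 to 0.325). That lies below the value predicted beforehand for DNA of XY cells, which leaves this explanation open. For RNA from other cell types, 76.9% of 854 long silent features (74 to 79.7) had a read. That share lies above the limit set beforehand for such RNA and below the limit set against it, so it is left open as well. These 2 tests do not tell the explanations apart, and opposite-strand reads of this library were not examined separately. No biological explanation was tested.

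Of the imprinted non-coding genes, Mirg was lower in the Clock/Bmal1 ESC clones before dox, with 4.91 against 115 CPM in the ClockBmal1DN clones, while Meg3 (2.05 against 23.4 CPM, -3.51 ± 0.573, adjusted p = 0.427) and Rian (34.5 against 459 CPM, -3.73 ± 0.493, adjusted p = 0.16) did not pass. Feeder RNA in the other libraries is argued against: in ClockBmal1DN clone 6 the median log2 change of the 3 genes with dox was 0.0256 times the mean change of the 17 feeder markers (-0.07 against -2.74). In 3 of 3 genes all 4 Clock/Bmal1 libraries lay below all 6 others, but the genes were picked for low values and the libraries come from 2 clones, so this count does not test for an outlying clone. The untreated control line, with the lowest feeder deviation of the ESC libraries (-1.572), had 18.04, 207.6 and 59.17 CPM. Line and transgene are the same split, so a biological difference between the lines stays open.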

How the results depend on the processing

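Values from legacy = FALSE, from fits without the control-line libraries and from fits without both libraries of a clone were added after the data were seen; all other alternatives here were planned. The cause was not tested for any of these changes unless it is stated. Counts below are genes that passed, and the counts with all libraries were 95, 1, 13 and 2 in ESC (Clock/Bmal1, ClockBmal1DN, their difference, untreated lines), 254, 1, 69 and 0 in iPSM, and 0 for iPSM minus ESC. With no low-count filter they were 537, 463, 410 and 45 in ESC, 597, 8, 280 and 221 in iPSM, and 87. With a mean of at least 1 CPM the differences gave 5 in ESC and 35 in iPSM. DESeq2 gave 355, 6, 130 and 9 in ESC, 157 for the iPSM difference, 25 for untreated iPSM and 15 for iPSM minus ESC. With legacy = FALSE Clock/Bmal1 in ESC gave 162 and the iPSM difference 32. On RPKM Clock/Bmal1 gave 59 in ESC and 70 in iPSM, ClockBmal1DN 0 in both, untreated ESC 1 and the iPSM difference 9. With only the groups compared, and so fewer residual degrees of freedom, Clock/Bmal1 gave 25 in ESC and 111 in iPSM, and ClockBmal1DN and untreated ESC gave 0. The clone block gave 158 (ESC Clock/Bmal1), 25 (ESC difference), 132 (iPSM difference) and 2 (iPSM minus ESC), and without the control line 154, 16 and 104 for ESC Clock/Bmal1, the ESC difference and the iPSM difference. Without both libraries of ESC ClockBmal1DN clone 6, ClockBmal1DN, the difference and untreated ESC gave 0. Without those of iPSM ClockBmal1DN clone 19, ClockBmal1DN gave 2 and the difference 2, and without those of iPSM Clock/Bmal1 clone 12 the Clock/Bmal1, difference and untreated counts were 1673, 830 and 4197. Fits without both libraries of a clone leave 1 clone of that line, assumed to vary like the others. Their counts therefore do not measure the spread between clones of that line. Of 132 list tests 29 were called, 2 with an estimated correlation and 6 with fry.

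Leaving out 1 library in turn gave 7 to 90 (ESC Clock/Bmal1), 0 to 2 (ClockBmal1DN), 0 to 8 (difference) and 1 to 2 (untreated) in ESC, 83 to 678, 1 to 2, 16 to 167 and 0 to 1779 in iPSM, 0 in all 8 fits for iPSM minus ESC and 23 to 36 list calls. Of the named genes called, 5 of 22 (ESC Clock/Bmal1), 0 of 9 (difference), 19 of 41 (iPSM Clock/Bmal1) and 6 of 23 (difference) were kept in all of these fits. RLE factors and no composition factors kept all gene counts within 1.5 times. For lists whose direction turned without 1 library, the adjusted p of that fit is given with the value from all libraries and the range of the left-out fits in brackets. These fits have no clone block and compare groups that hold different clones, so a turned direction can come from differences between clones. Feeder in ESC Clock/Bmal1 turned without untreated clone 7, 0.0241 [0.974, 0.0161 to 0.168]. In iPSM Clock/Bmal1 naive pluripotency (0.901 [0.04, 0.000183 to 0.97]), stress response (0.0306 [0.244, 8.13e-08 to 0.571]) and cell cycle (0.0306 [0.971, 0.00228 to 0.736]) turned without untreated clone 12. Cholesterol turned without untreated clone 20 (0.0161 [0.894, 0.0161 to 0.736]). In ClockBmal1DN iPSM mitochondrially encoded (0.00493 [0.861, 0.00374 to 0.277]) and hypoxia genes (0.0166 [0.364, 0.000151 to 0.572]) turned without untreated clone 7.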

Other observations

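The genes of this part were chosen after their values were seen, and its comparison of calls between cell types was made only after the result was seen. Among the 68 genes that rose with Clock/Bmal1 in both cell types were clock genes outside the naming rule: Cry1, a clock repressor (1.87 ± 0.258 in ESC and 1.20 ± 0.163 in iPSM, log2 ± SE), Bhlhe40, also called Dec1 (2.52 ± 0.367 and 2.84 ± 0.291), and Nr1d2, which encodes REV-ERB beta (1.86 ± 0.228 and 1.33 ± 0.191). Receptors and adhesion proteins of neurons were among them too: Ntrk2, the BDNF receptor gene (3.80 ± 0.398 and 5.05 ± 0.514), Epha8, an ephrin receptor gene (3.69 ± 0.375 and 4.84 ± 0.381), Lingo1 (4.61 ± 0.627 and 3.47 ± 0.348) and Islr2 (3.98 ± 0.436 and 5.12 ± 0.758). Insrr, an insulin-receptor-related gene, had 4.37 ± 0.657 and 5.25 ± 0.828.

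Developmental regulators also rose in both: Sox8 (4.01 ± 0.398 and 4.36 ± 0.367), Scx, a tendon bHLH gene (3.85 ± 0.633 and 4.61 ± 0.488), Foxo3 (2.47 ± 0.237 and 1.99 ± 0.211) and the imprinted gene Dlk1 (5.00 ± 0.779 and 5.02 ± 0.457). Transporters and channels were Slc30a1, a zinc exporter gene (1.55 ± 0.197 and 1.33 ± 0.206), Aqp3, an aquaglyceroporin gene (3.01 ± 0.396 and 4.10 ± 0.388), and Trpm1 (4.70 ± 0.582 and 2.11 ± 0.33). Of the genes tested in both cell types, all 91 up in ESC had a positive value in iPSM (median 2.73), and 236 of 244 up in iPSM had a positive value in ESC (median 1.65, fitted values that include genes with few counts). No theme was tested for these genes.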
